A study of Oryza sativa with 12 samples.

How the data were processed

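RNA of rice suspension cells treated with a chitin oligosaccharide at 1 ppm was compared with RNA of untreated cells on 12 arrays of 2 colours, with 2 biological replicates per the labels at each of 6 times between 1 and 12 h. Treated RNA carried Cy5 and untreated RNA Cy3 on every array, per the labels, so that a ratio of Cy5 over Cy3 gives treated over untreated RNA. The labels do not say whether the untreated RNA was taken anew at each time. If it was not, time in culture is part of each value against untreated RNA.

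Spot intensity and local background intensity were read from the deposited scanner files, which hold mean pixel brightness on a linear scale with no normalization, made with Agilent Feature Extraction 9.5.3.1 per the file headers. The same files hold processed signals, which per the file headers had been detrended, dye-normalized and given surrogate values near background. The log10 ratio that the authors deposited as their values equalled the scanner software's log10 ratio on every array, with a largest difference of 0, so its scale and direction were known, and its column medians lay between -0.0333 and 0. The arrays lay on 3 slides read in 3 scans. Slide 1 held replicate 1 of 1 to 6 h, slide 3 held replicate 2 of 1 to 6 h, and slide 2 held both replicates of 8 and 12 h. The local background was 45 to 50 in Cy3 and 53.5 to 56 in Cy5, and between 8 and 82 spots per array were marked as outliers.

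Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess, in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). Control spots had weight 0 in loess and were left out afterwards, as were spots marked as outliers. Spots of the same probe were averaged, and a gene was represented by its brightest probe over both channels, treated RNA included. Of 7004 genes with over 1 probe kept, at most 1 at any time had probes changed at least 2-fold in opposite directions. Of the 76 genes named, 36 had over 1 probe kept, and in 14 of these the probes lay at least 1 log2 unit apart at some time. They were Os01g0826400, Os02g0462800, Os02g0570400, Os02g0627100, Os04g0107600, Os04g0178300, Os04g0179200, Os04g0179700, Os05g0322900, Os05g0343400, Os06g0569500, Os06g0726200, Os10g0542900 and Os12g0448900, whose sizes of change depend on the probe taken. Except for Os05g0322900, the size given with its SE at a time was the highest among the gene's probes, so that the other probes rose less. Genes kept their locus and annotation text from the scanner files. This text can be old and can name a protein of another species. 293 probe sequences were shared by more than 1 gene. A probe was kept where it was well above background in Cy3 or in Cy5 on both arrays of at least 1 time, which gave 24914 genes, with 113 single values missing.

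A single limma model with a mean for each of the 6 times was fitted to all arrays, so that the times shared an estimate of the spread, with 6 residual and 2.75 prior degrees of freedom. Each time was tested against 0, each pair of consecutive times by its difference, and all times by the moderated F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a gene was not well above background in untreated RNA on either array of a time, the change was given as a bound. The bound set the mean treated signal against the higher of the lowest signal among measured probes and the gene's own signal, per channel after loess and Aquantile, and it is open to dye bias because no dyes were exchanged.

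Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took a panel of 53 genes, of which 48 were used, the 12 largest rises and falls at each time, the 6 largest each way between consecutive times and the 4 members of each list with the smallest adjusted p at each time. Among the genes that the rule allowed, those named were chosen after their values and the results with arrays left out had been seen. Several whose call ended without 1 array were exchanged for others, so that the named genes overstate how often a call held. Lists were drawn by words in the annotation text, and in part by locus. They covered WRKY, NAC, AP2/ERF and MYB transcription factors, JAZ/TIFY repressors, jasmonate, phenylpropanoid, shikimate, MEP and diterpenoid phytoalexin biosynthesis, chitinases, beta-1,3-glucanases, other pathogenesis-related proteins, class III peroxidases, glutathione S-transferases, glucosyltransferases and cytochrome P450. Further lists were receptor-like kinases, the MAP kinase cascade, calcium signalling, E3 ubiquitin ligases, protein folding in the endoplasmic reticulum, auxin response, cell wall expansion, cell division, ribosomal proteins, photosynthesis, heat shock, sugar starvation and respiratory burst with antioxidant enzymes. Lists were tested with camera at a preset correlation between genes of 0.01, and also with an estimated correlation and with fry, on the genes without missing values (112 genes left out). 7 of the 14 diterpenoid genes stood in another list too.

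The fit was tested on simulated data with 24802 genes and the spread of the real ones, 50 genes being changed at each size. The noise was independent between genes and between arrays, with no deviations shared by replicate or slide. For the comparison at 1 h the fit recovered 52% of genes set to a 1.5-fold change, 84% at 2-fold and 100% at 4-fold. For the step from 6 to 8 h it recovered 48% at 2-fold and 90% at 4-fold. Each simulated gene had the same spread at all times. In the real data the median absolute deviation between replicates was 0.35 and 0.335 at 6 and 8 h, against 0.149 at 1 h. Recovery for the step from 6 to 8 h can therefore be overstated. Far fewer genes were changed than in the real data, where 40.8% were called at 1 h, so that the adjustment also differed. A list of 30 genes shifted by 1 log2 unit had an adjusted p of 1.82e-101 with the preset correlation, 5.42e-05 with an estimated one and 4.57e-08 with fry. Because the simulated genes were not correlated, these values do not show the power for real lists. Of the real lists, 0 of 180 tests at single times passed with an estimated correlation. Alternatives were no background correction, the processed signals, the deposited values, median centring, Aquantile, other filters on dim probes, outlier spots kept, the mean over probes, eBayes with trend and robust settings, the slide or the replicate number as a block, each time fitted alone, stricter thresholds and leaving out each array. A range of adjusted p over all alternatives includes, for lists, fry and the estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python. No genome coordinates were used here.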

Results

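Rice suspension cells of the cultivar Nipponbare, grown in the dark, were treated with a chitin oligosaccharide at 1 ppm, a fragment of the fungal cell wall polymer that plant cells perceive as a sign of infection. RNA was compared with that of untreated cells on 12 Agilent arrays of 2 colours, with 2 biological replicates at each of 6 times, which were 1, 2 and 4 h in the early part and 6, 8 and 12 h in the later part of the series. Every array carried treated RNA in Cy5 and untreated RNA in Cy3. The median spot signal of the arrays lay between 352.4 and 444.6 in Cy3 and between 698.4 and 1118.4 in Cy5, and 73.1% to 80.8% of gene spots were well above background in Cy3. Over the 24914 genes tested, the log2 ratios of the replicates had a Pearson correlation across genes of 0.968 at 1 h, 0.985 at 2 h, 0.982 at 4 h, 0.955 at 6 h, 0.946 at 8 h and 0.945 at 12 h, where genes are not independent replicates. Gene values are given as mean log2 ratios of treated over untreated RNA ± SE of the limma fit, n = 2 arrays per time. The SE rests on 1 spread pooled over all times and is not the spread of the 2 arrays of a time. The median absolute deviation between replicates was 0.149, 0.146, 0.189, 0.35, 0.335 and 0.249 at the times in order. SEs and p-values at the late times can therefore be too small. The number of arrays limits the precision, and the p-values measure the spread between the samples that the labels name biological replicates. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. With each time fitted alone, 12944, 18306, 18737, 13960, 11727 and 11182 genes were called at the times in order. The median log2 ratio of all genes at a time lay between 0.004 and 0.033, between 0.088 and 0.179 with median centring in place of loess, and between -0.216 and -0.096 with the processed signals of the scanner software. No array had its dyes exchanged, so that a dye effect of a single probe is part of each value against untreated RNA and cancels between times.

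**Figure D1:**
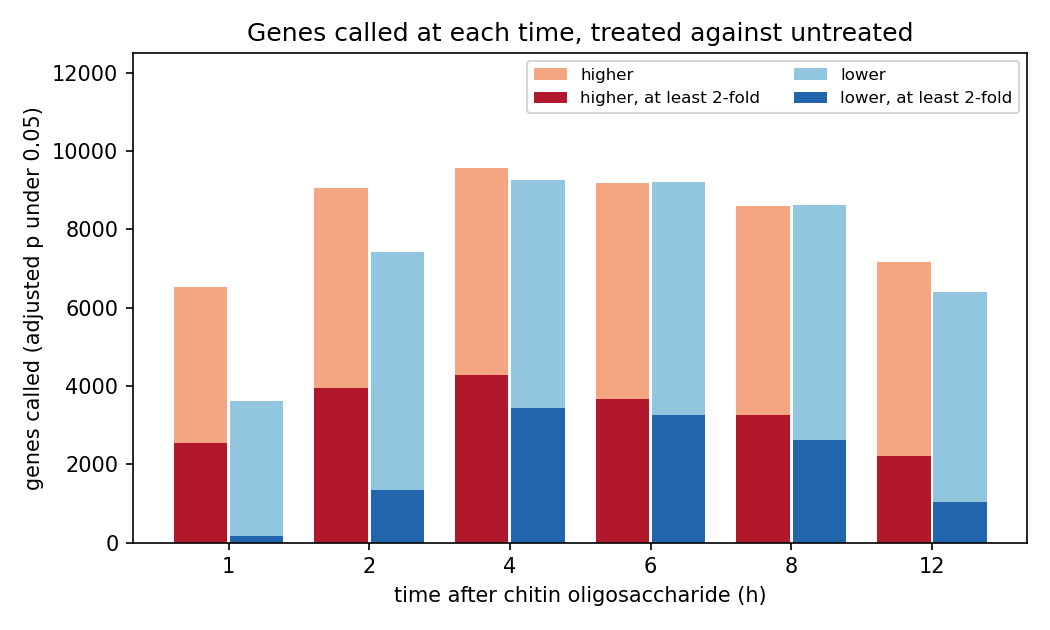
Number of genes called (limma, adjusted p under 0.05) with a higher or lower ratio of treated over untreated RNA at each time in h, with the darker part of each bar for genes changed at least 2-fold. At 1 h 2537 genes were at least 2-fold higher and 169 at least 2-fold lower, against 4276 and 3440 at 4 h.

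The first comparison asked which transcripts had changed 1 h after the oligosaccharide was added. Genes of several families of regulatory proteins rose. Os04g0301500, a basic helix-loop-helix protein, rose by 7.58 ± 0.12, and Os01g0841700, annotated as RPP17-1, by 6.94 ± 0.20. Os02g0559800, a RING domain protein, stood at 8.35 ± 0.43, with its untreated signal above background on 1 of the 2 arrays. Of the WRKY family, transcription factors known from plant defence, 43 of 65 genes rose and 1 fell. Among the rises were WRKY 42 (Os02g0462800) at 5.99 ± 0.29 and on its other probe at 3.53, and WRKY 28 (Os06g0649000) at 5.96 ± 0.39. WRKY 24 (Os01g0826400) stood at 5.20 ± 0.30, or 3.56 on its lowest probe, and WRKY 53 (Os05g0343400) at 3.98 ± 0.25, or 2.99 on its other probe. The family's median was 0.83, and 44 genes passed adjusted over the list alone (camera adjusted p = 3.91e-08, and adjusted p = 0.213 with an estimated correlation). The JAZ/TIFY proteins, which repress jasmonate responses, rose in 12 of 14 genes, 12 of them adjusted over the list alone, with a median of 2.52 (adjusted p = 5.15e-09, and adjusted p = 0.145 with an estimated correlation). Among them were the ZIM domain proteins Os10g0391400 at 5.76 ± 0.19, Os03g0181100 at 5.72 ± 0.14 and Os10g0392400 at 5.55 ± 0.16. 33 of 48 genes of the list of E3 ubiquitin ligases rose and 2 fell, 38 being called adjusted over the list alone, with a median of 1.16 (adjusted p = 1.06e-09, and adjusted p = 0.125 with an estimated correlation). The list held 40 U-box proteins. For the NAC factors 28 of 50 rose and 3 fell, 33 passing adjusted over the list alone, at a median of 0.73 (adjusted p = 9.12e-05, and adjusted p = 0.213 with an estimated correlation). For the AP2/ERF factors 38 of 72 rose and 6 fell, 46 passing adjusted over the list alone, at a median of 0.32 (adjusted p = 0.000109, and adjusted p = 0.112 with an estimated correlation). Receptor-like kinases rose in 56 of 103 genes and fell in 6, 63 of them adjusted over the list alone, with a median of 0.37 (adjusted p = 6.31e-05, and adjusted p = 0.112 with an estimated correlation). The LysM domain receptor-like kinase 3 (Os08g0538300) was at 0.91 ± 0.096 and MAP kinase MAPK5a (Os03g0285800), a kinase of the defence cascade, at 3.76 ± 0.19. Os09g0522000, a CBF-like protein of the AP2 type, rose by 3.46 ± 0.37. Among the falls, a phosphoenolpyruvate carboxylase kinase (Os04g0517500) stood at -2.04 ± 0.34 and the helix-loop-helix protein Os08g0536800 at -2.03 ± 0.16. In all 10159 genes were called, 6534 higher and 3625 lower, and 2706 of them were changed at least 2-fold. Agilent's processed signals gave 4797 higher and 8027 lower, and leaving out the 1 h array of replicate 1 or of replicate 2 left 5989 and 5571 calls. Without the filter on dim probes the medians were 0.53 for WRKY, 0.21 for NAC and 0.21 for receptor-like kinases, and the AP2/ERF median was 0.15 with processed signals and 0.51 with median centring.

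At 2 h genes of phenolic metabolism and chitinases, enzymes that cleave chitin, were higher, as they had been at 1 h with smaller medians. Phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway, rose in Os05g0427400 by 6.45 ± 0.15. In Os02g0627100 it rose by 5.22 ± 0.18, or 3.1 on the other probe. Cinnamate 4-monooxygenase (Os05g0320700), the next step, rose by 2.50 ± 0.21. 25 of 31 phenylpropanoid genes rose and 1 fell, 26 adjusted over the list alone, with a median of 2.79 (camera adjusted p = 3.1e-07, and adjusted p = 0.145 with an estimated correlation). The shikimate pathway, which supplies phenylalanine, had 27 of 39 genes higher and 3 lower, 30 adjusted over the list alone, with a median of 1.00 (adjusted p = 6.62e-05, and adjusted p = 0.145 with an estimated correlation). Chitinases rose in 24 of 29 genes and fell in 1, 25 adjusted over the list alone, with a median of 2.86 (adjusted p = 5.32e-07, and adjusted p = 0.125 with an estimated correlation). Os10g0542900, a chitinase, stood at 5.28 ± 0.23, or 1.52 on its other probe, and the endochitinase Os06g0726200 at 2.56 ± 0.14, or 1.41 on its lowest probe. Of the jasmonate biosynthesis genes 19 of 24 rose and 1 fell, 20 adjusted over the list alone, with a median of 1.33 (adjusted p = 3.64e-05, and adjusted p = 0.112 with an estimated correlation). Os08g0459600, annotated as oxophytodienoate reductase 3, was at 2.25 ± 0.11 and allene oxide cyclase (Os03g0438100) at 1.10 ± 0.076. Signalling lists were also higher. 20 of 32 genes of the MAP kinase cascade rose and 6 fell, 26 adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0109, and adjusted p = 0.278 with an estimated correlation). For calcium signalling 94 of 162 rose and 36 fell, 132 adjusted over the list alone, at a median of 0.40 (adjusted p = 0.00258, and adjusted p = 0.19 with an estimated correlation). Germin-like protein 6 (Os08g0189600) rose by 7.08 ± 0.20, the protein kinase Os01g0699500 by 6.83 ± 0.23, a soluble pyrophosphatase (Os01g0974700) by 6.65 ± 0.23 and the ethylene-responsive element binding protein Os02g0654700 by 6.21 ± 0.23. An arginine decarboxylase (Os04g0107600), an enzyme of polyamine synthesis, had an untreated signal not well above background. On its brightest probe it was 26.4-fold higher (limma adjusted p = 1.4e-07), which is also that probe's plain ratio (log2 4.72). The other probe had a smaller log2 ratio of 3.40, so that 26.4-fold is not a minimum for the gene. Genes of cell division were among the falls, with the cyclins Os12g0588800 and Os09g0111100 at -3.30 ± 0.27 and -2.87 ± 0.37. Other genes fell too. The AUX1-like proteins Os10g0147400 and Os03g0244600, of a family of auxin carriers, stood at -3.13 ± 0.53 and -3.02 ± 0.33, and the protein kinase Os08g0117700 at -4.13 ± 0.30. In the cell division list 80 of 139 genes fell and 20 rose, 100 adjusted over the list alone, with a median of -0.38 (adjusted p = 2.96e-05, and adjusted p = 0.432 with an estimated correlation). In all 16477 genes were called, 9059 higher and 7418 lower, 5297 of them by at least 2-fold, and processed signals gave 6949 higher and 10947 lower. With processed signals the medians were 2.03 for jasmonate biosynthesis, 0.39 for the MAP kinase cascade, 0.23 for calcium signalling and -0.66 for cell division, against -0.12 for cell division with median centring, and without the filter on dim probes 1.86 for phenylpropanoid, 0.62 for shikimate and 0.25 for calcium signalling genes. Lists were not confined to the time at which they are described. On the 1 h arrays of replicates 1 and 2 the medians were 1.43 and 1.65 for chitinases and 1.44 and 1.21 for phenylpropanoid genes. For jasmonate biosynthesis they were 0.58 and 0.83. On the 2 h arrays they were 1.25 and 1.27 for WRKY, 3.26 and 3.67 for JAZ/TIFY and 1.43 and 1.51 for E3 ubiquitin ligases. JAZ/TIFY genes still stood at 2.00 and 1.71 at 12 h.

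**Figure D2:**
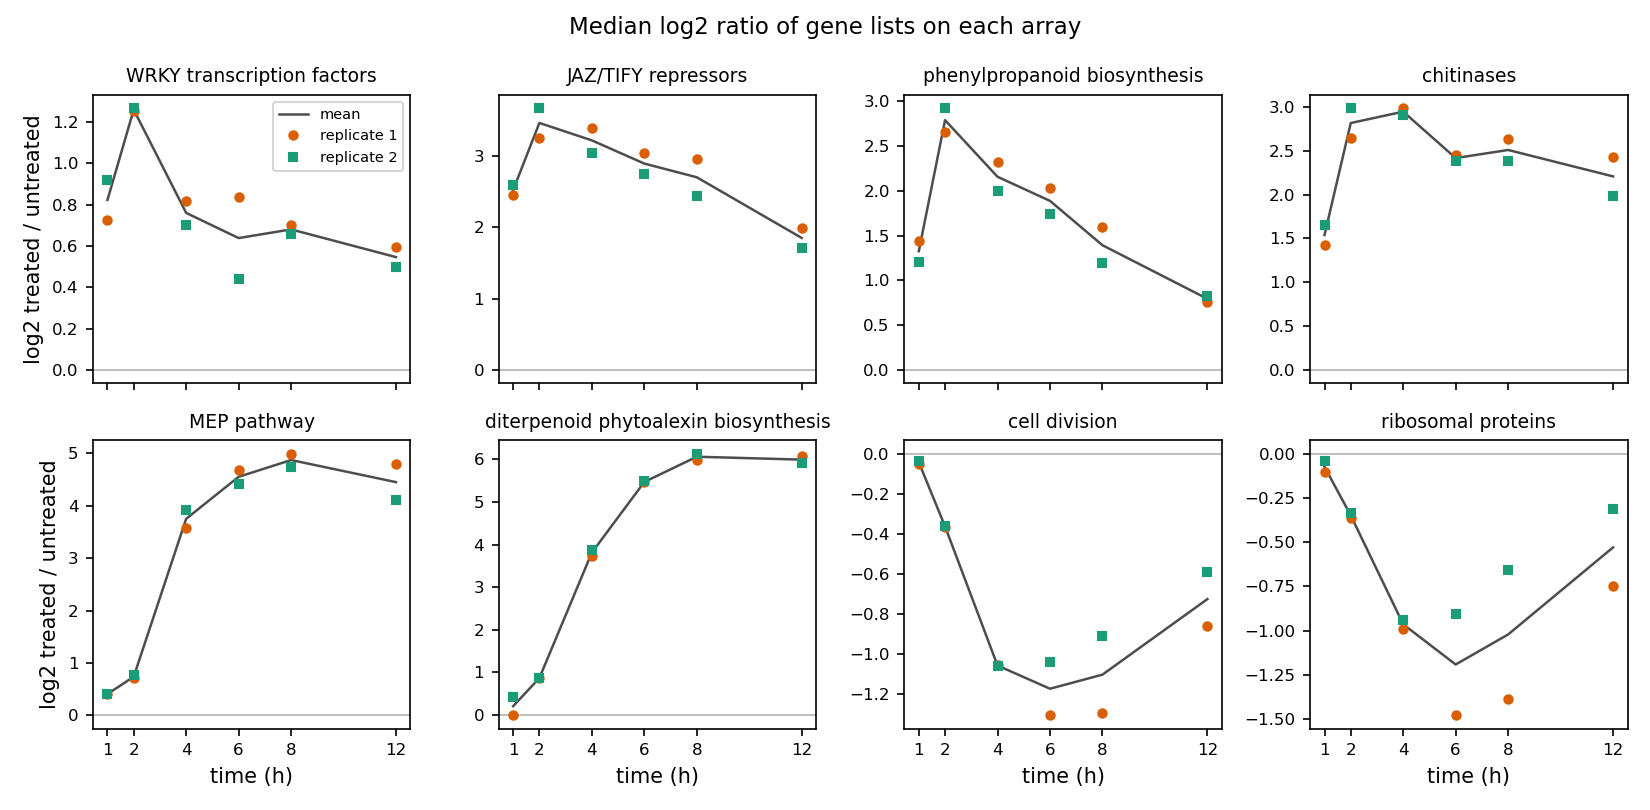
Median log2 ratio of treated over untreated RNA of 8 gene lists against time in h, with points for the single arrays of replicates 1 and 2 and a line through the mean of both. The medians of the diterpenoid and MEP lists passed 3 by 4 h, while those of ribosomal proteins and cell division lay below 0 on every array, with smaller changes in replicate 2 than in replicate 1 at 6, 8 and 12 h, although with median centring they stood above 0 at 1 h (0.32 and 0.21) and that of ribosomal proteins also at 2 h (0.12).

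At 4 h genes of diterpenoid synthesis were among the largest rises. Rice makes its diterpenoid phytoalexins, antimicrobial compounds, from geranylgeranyl diphosphate, which the plastid MEP pathway supplies. The cytochrome P450 gene Os04g0180400 rose by 7.95 ± 0.097. Its annotation text, CYP99A1, is shared by Os04g0178400 and does not tell the 2 genes apart. The terpene synthase Os04g0179700 rose by 7.29 ± 0.18 and the copalyl diphosphate synthetase Os04g0178300 by 5.13 ± 0.10. The dehydrogenase-like Os04g0179200 rose by 7.26 ± 0.099, or 2.13 on its lowest probe. An ent-kaurene oxidase (Os06g0569500) stood at 6.84 ± 0.12, or 4.53 on its other probe, and the terpene synthase Os02g0570400 at 5.44 ± 0.10. 12 of the 14 genes of the diterpenoid phytoalexin list rose and 2 did not pass, 12 being called adjusted over the list alone, with a median of 3.81 (camera adjusted p = 5.12e-06, and adjusted p = 0.156 with an estimated correlation). All 9 genes of the MEP pathway rose, also adjusted over the list alone, with a median of 3.77 (adjusted p = 4.64e-05, and adjusted p = 0.252 with an estimated correlation). Os07g0190000, annotated as deoxyxylulose phosphate synthase 2 of the pathway's entry step, was at 4.41 ± 0.15. The reductoisomerase (Os01g0106900) was at 3.85 ± 0.15 and the methylerythritol kinase (Os01g0802100) at 2.74 ± 0.17. Genes of protein folding in the endoplasmic reticulum rose in 18 of 23 cases and fell in 1, 20 adjusted over the list alone, with a median of 1.04 (adjusted p = 2.76e-05, and adjusted p = 0.145 with an estimated correlation). The endosperm lumenal binding protein Os02g0115900, a chaperone of this compartment, stood at 5.04 ± 0.16. Glutathione S-transferases, detoxifying enzymes, rose in 36 of 63 genes and fell in 13, 49 adjusted over the list alone, with a median of 0.63 (adjusted p = 0.00482, and adjusted p = 0.145 with an estimated correlation). Cytochrome P450 genes, 9 of which stood in another list too, rose in 98 of 193 cases and fell in 45, 143 adjusted over the list alone, with a median of 0.31 (adjusted p = 0.0119, and adjusted p = 0.202 with an estimated correlation), a call that median centring ended (adjusted p = 0.441, where all alternatives ranged from 5.97e-07 to 0.441), while processed signals gave a median of 0.53. Os12g0448900, annotated as an animal haem peroxidase family protein, was at 6.69 ± 0.27, or 5.01 on its other probe. The Bowman Birk trypsin inhibitor Os01g0124200 was at 6.61 ± 0.36 and the alpha-amylase Os08g0473900 at 4.78 ± 0.49. Falls of at least 2-fold numbered 3440 genes. The AUX1-like Os10g0147400 stood at -5.16 ± 0.53 and the endoglucanase Os01g0312800 at -4.28 ± 0.35. 222 of 246 ribosomal protein genes fell and 5 rose, 229 adjusted over the list alone, with a median of -0.96 (adjusted p = 1.36e-13, and adjusted p = 0.45 with an estimated correlation). In all 18837 genes were called, 9569 higher and 9268 lower, 7716 of them by at least 2-fold, and median centring gave 11498 higher and 7284 lower and processed signals 8417 and 10733. The ribosomal median was -0.42 with median centring, and without the filter on dim probes the medians were 0.27 for glutathione S-transferases and 0.06 for cytochrome P450.

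**Figure D3:**
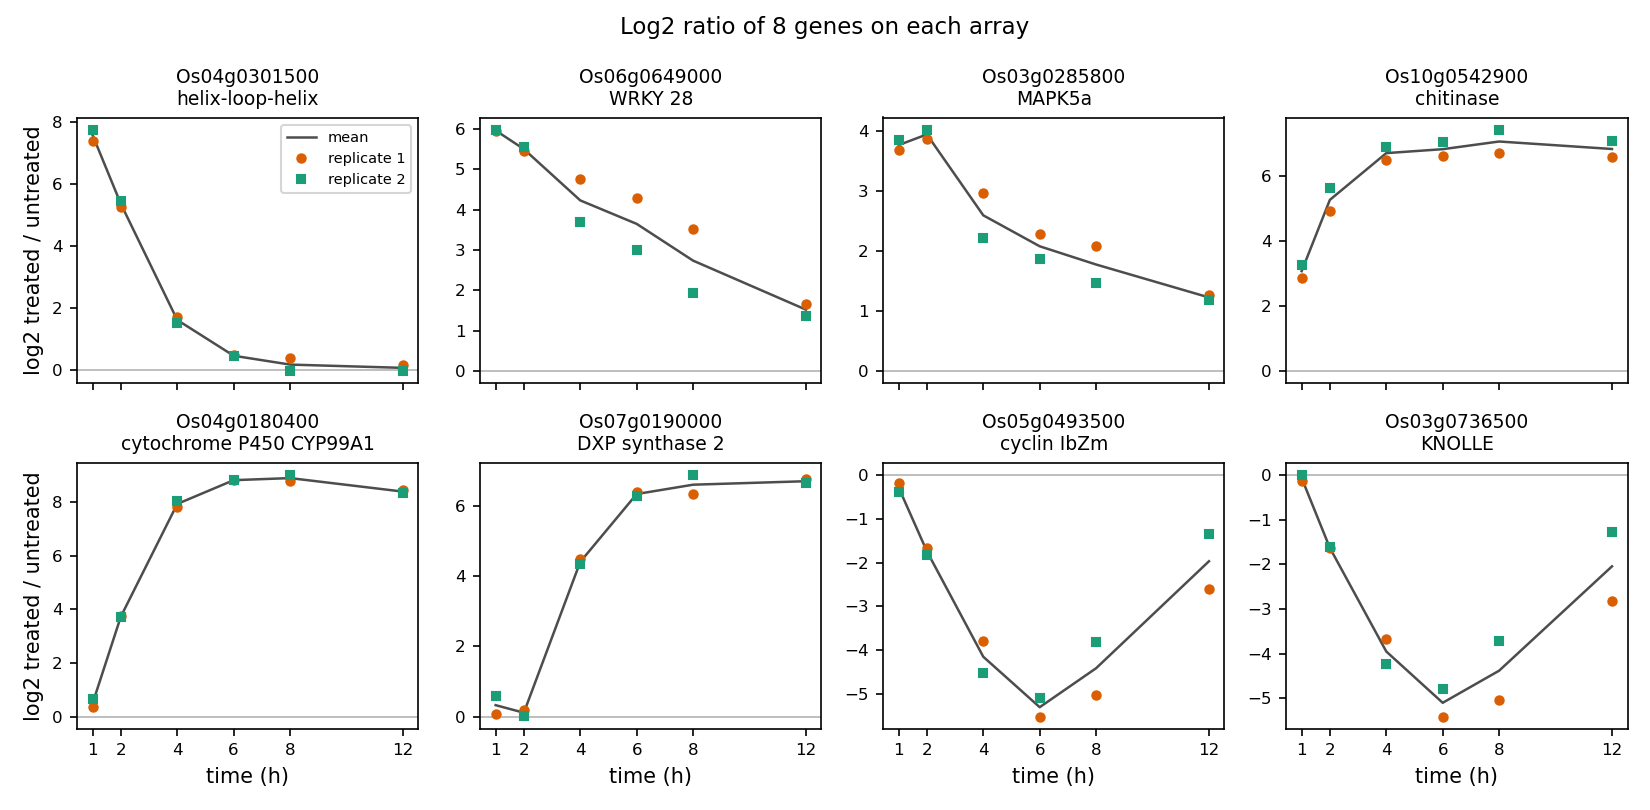
Log2 ratio of treated over untreated RNA against time in h for 8 genes, with points for the arrays of replicates 1 and 2 and a line through the mean. The basic helix-loop-helix gene Os04g0301500 was at 7.58 at 1 h and 0.08 at 12 h, while the cytochrome P450 gene Os04g0180400 was at 7.95 at 4 h and 8.41 at 12 h.

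At 6 h genes of diterpenoid synthesis were high and genes of cell division and of the ribosome were lower. Os04g0180400 was at 8.83 ± 0.097, Os04g0179700 at 7.65 ± 0.18, Os02g0570400 at 6.92 ± 0.10 and Os07g0190000 of the MEP pathway at 6.34 ± 0.15. 12 of 14 diterpenoid genes rose (12 adjusted over the list alone), with a median of 5.45 (camera adjusted p = 1.61e-07, and adjusted p = 0.145 with an estimated correlation). The 9 MEP genes, all higher and all called adjusted over the list alone, had a median of 4.55 (adjusted p = 2.48e-06, and adjusted p = 0.209 with an estimated correlation). A chalcone synthase (Os04g0103900), the first enzyme of flavonoid synthesis, was at least 10.3-fold higher (adjusted p = 9.23e-08), its untreated signal not being well above background. Of proteins of the PR-10 type, PBZ1 (Os12g0555500) stood at 4.17 ± 0.21 and the Bet v I protein Os12g0555000 at 5.09 ± 0.25. Among the falls were genes used in mitosis and cytokinesis. Cyclin IbZm (Os05g0493500) stood at -5.30 ± 0.34, cyclin IaZm (Os01g0805600) at -4.88 ± 0.31, the cytokinesis syntaxin KNOLLE (Os03g0736500) at -5.10 ± 0.38, the HMG box protein Os02g0258200 at -5.26 ± 0.39 and the microtubule-binding EB1 protein Os10g0498900 at -5.14 ± 0.42. In the cell division list, which held 11 cyclin-dependent kinase entries, 108 of 139 genes fell and 15 rose, 123 adjusted over the list alone, with a median of -1.15 (adjusted p = 2.03e-11, and adjusted p = 0.269 with an estimated correlation). Ribosomal protein genes fell in 231 of 246 cases and rose in 4, 237 adjusted over the list alone, with a median of -1.20 (adjusted p = 2.08e-16, and adjusted p = 0.409 with an estimated correlation). The single arrays, each on a slide of its own at this time, gave ribosomal medians of -1.48 in replicate 1 and -0.90 in replicate 2. In all 18373 genes were called, 9169 higher and 9204 lower, 6929 of them by at least 2-fold. Median centring gave 11475 higher and 7409 lower, and processed signals 8319 and 10323. With median centring the medians were -0.67 for ribosomal proteins and -0.76 for cell division.

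At 8 h genes of the diterpenoid and MEP pathways were again among the largest rises. The cytochrome P450 genes Os02g0569900 and Os04g0178400 stood at 7.20 ± 0.20 and 6.30 ± 0.26, and the terpene synthase Os02g0571100 at 5.80 ± 0.16. The cytochrome P450 gene Os02g0570700, not well above background in untreated cells, was at least 16.5-fold higher (adjusted p = 3.15e-08). 13 of 14 diterpenoid genes rose (13 adjusted over the list alone) with a median of 6.09 (camera adjusted p = 2.91e-09, and adjusted p = 0.125 with an estimated correlation). The 9 MEP genes were all higher and called adjusted over the list alone, with a median of 4.87 (adjusted p = 4.74e-07, and adjusted p = 0.191 with an estimated correlation). WRKY 45 (Os05g0322900) was at 2.46 ± 0.20 and WRKY 53 (Os05g0343400) at 2.52 ± 0.25. Histone genes, used when DNA is replicated, were among the falls, with histone H3 (Os06g0160100) at -4.60 ± 0.27 and histone H2B.2 (Os08g0490900) at -4.56 ± 0.29. A YABBY family protein (Os04g0536300) stood at -4.81 ± 0.46. 106 of 139 cell division genes fell and 11 rose, 119 adjusted over the list alone, with a median of -1.09 (adjusted p = 3.51e-13, and adjusted p = 0.236 with an estimated correlation). 229 of 246 ribosomal protein genes fell and 2 rose, 231 adjusted over the list alone, with a median of -1.04 (adjusted p = 2.08e-16, and adjusted p = 0.409 with an estimated correlation). Both 8 h arrays lay on 1 slide, with ribosomal medians of -1.39 in replicate 1 and -0.66 in replicate 2, so that the median without replicate 1 was -0.66. In all 17216 genes were called, 8602 higher and 8614 lower, 5884 of them by at least 2-fold. Median centring gave 11149 higher and 7205 lower, and processed signals 7633 and 9936. With median centring the ribosomal median was -0.53.

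At 12 h an early regulator no longer passed the test, while genes of diterpenoid synthesis were high. The helix-loop-helix gene Os04g0301500 was at 0.08 ± 0.12, which did not pass, and MAPK5a (Os03g0285800) at 1.22 ± 0.19, while Os04g0180400 was at 8.41 ± 0.097, Os04g0178400 at 7.12 ± 0.26 and Os07g0190000 at 6.70 ± 0.15. A multicopper oxidase (Os10g0346300) rose by 6.62 ± 0.24. 13 of 14 diterpenoid genes rose (13 adjusted over the list alone), at a median of 5.99 (camera adjusted p = 3.15e-12, and adjusted p = 0.119 with an estimated correlation), and all 9 MEP genes rose, also adjusted over the list alone, at a median of 4.45 (adjusted p = 8.32e-09, and adjusted p = 0.151 with an estimated correlation). Chitinases were higher in 22 of 29 genes and lower in 4, 26 adjusted over the list alone, with a median of 2.22 (adjusted p = 4.74e-07, and adjusted p = 0.125 with an estimated correlation). The list of other pathogenesis-related proteins rose in 46 of 94 genes and fell in 17, 63 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00134, and adjusted p = 0.231 with an estimated correlation, and adjusted p = 0.0687 with median centring, where all alternatives ranged from 1e-05 to 0.231). Its word search for thionins had also taken in 38 annotations with the word methionine, which are not defence proteins by that name. PBZ1 (Os12g0555500) stood at 5.59 ± 0.21. Among the falls were the YABBY protein Os04g0536300 at -4.07 ± 0.46, the aldose epimerase Os02g0575800 at -3.88 ± 0.24 and the ubiquitin domain protein Os09g0452700 at -3.56 ± 0.55. 96 of 139 cell division genes fell and 10 rose, 109 adjusted over the list alone, at a median of -0.72 (adjusted p = 1.36e-13, and adjusted p = 0.231 with an estimated correlation). For ribosomal proteins 134 of 246 fell and 2 rose, 139 adjusted over the list alone, at a median of -0.52 (adjusted p = 8.29e-12, and adjusted p = 0.48 with an estimated correlation). Within the slide that held both 12 h arrays the ribosomal medians were -0.75 and -0.31 in replicates 1 and 2. In all 13574 genes were called, 7171 higher and 6403 lower, 3247 of them by at least 2-fold, and processed signals gave 5960 higher and 8264 lower. Without the 12 h array of replicate 1 the count was 6831 and the ribosomal median -0.31, against -0.14 with median centring, and the medians without the filter on dim probes were 0.91 for chitinases and 0.15 for the pathogenesis-related list.

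Differences between times were tested directly, in contrasts in which dye effects common to all arrays cancel. From 1 to 2 h, Os04g0179700 rose by 3.80 ± 0.26, Os04g0180400 by 3.24 ± 0.14 and the chitinase Os10g0542900 by 2.20 ± 0.33, its other probe having stood at 0.63 and 1.52. Os04g0301500 changed by -2.21 ± 0.17. Phenylpropanoid genes moved up by a median of 0.77, with 14 of 31 called and 16 adjusted over the list alone (adjusted p = 1.17e-06, and adjusted p = 0.248 with an estimated correlation). In all 4236 genes differed, 2615 higher and 1621 lower at 2 h. This count was 1341 and 905 without the 1 h arrays of replicates 1 and 2, and 1812 and 667 without the 2 h arrays, and the phenylpropanoid median was 0.51 without the filter on dim probes.

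From 2 to 4 h genes of the diterpenoid and MEP pathways rose. Os04g0179100, a glucose/ribitol dehydrogenase family protein, rose by 4.52 ± 0.18, Os07g0190000 by 4.30 ± 0.21 and Os02g0570400 by 4.18 ± 0.15. Diterpenoid genes were higher in 12 of 14 cases (12 adjusted over the list alone), with a median difference of 2.63 (adjusted p = 1.48e-14, and adjusted p = 0.24 with an estimated correlation), and MEP genes in 8 of 9 (9 adjusted over the list alone), with 2.95 (adjusted p = 2.19e-11, and adjusted p = 0.241 with an estimated correlation). Os04g0301500 changed by -3.75 ± 0.17, a NUDIX hydrolase (Os02g0520100) by -3.52 ± 0.26 and the glutelin family protein Os12g0283400 by -3.69 ± 0.45. In all 6939 genes differed, 2422 higher and 4517 lower at 4 h, against 3034 and 2733 with processed signals and 3223 and 3314 with median centring. Without the 2 h arrays of replicates 1 and 2 the count was 2644 and 2379, and without the 4 h arrays 3818 and 1745.

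From 4 to 6 h the terpene synthase Os02g0571100 rose by 2.41 ± 0.22 and Os07g0190000 of the MEP pathway by 1.93 ± 0.21, while a coumarate-CoA ligase-like protein (Os04g0683700) changed by -2.25 ± 0.13. The adjusted p of Os02g0571100 and Os07g0190000 was 0.0657 and 0.101 without the 4 h array of replicate 1 and 0.0513 and 0.0618 without that of replicate 2, that of Os07g0190000 was 0.0718 without the 6 h array of replicate 2, and that of Os02g0571100 was 0.0786 with processed signals. Over all alternatives the adjusted p ranged from 0.00451 to 0.0786 for Os02g0571100 and from 0.00674 to 0.101 for Os07g0190000. 8 of 14 diterpenoid genes were higher (11 adjusted over the list alone), with a median difference of 1.06 (adjusted p = 5.56e-16, and adjusted p = 0.24 with an estimated correlation). In all 243 genes differed, 70 higher and 173 lower at 6 h, against 22 and 27 with processed signals and 268 and 574 with the replicate number as a block. The count was 6 and 20 without the 4 h arrays of replicates 1 and 2, 12 without the 6 h array of replicate 2 (7 higher and 5 lower), 86 without either 1 h array and 107 without either 2 h array. From 6 to 8 h limma called 0 genes, with 1903 at an unadjusted p under 0.05, 1 call with processed signals and 2 with the deposited table. Camera called 13 of 30 lists in this step, 5 up and 8 down, 0 of them with a called member, and 0 with an estimated correlation. The lowest adjusted p values were those of the diterpenoid list, with 0 of 14 genes called (9 adjusted over the list alone) and a median difference of 0.46 (adjusted p = 4.12e-10, and adjusted p = 0.24 with an estimated correlation), and of the phenylpropanoid list, with 0 of 31 called (8 adjusted over the list alone) and a median of -0.39 (adjusted p = 8.2e-10, and adjusted p = 0.24 with an estimated correlation). In this step slide and time cannot be told apart.

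From 8 to 12 h, within 1 slide, 5 genes differed, all lower at 12 h, with 4511 genes at an unadjusted p under 0.05, while median centring also called 1 higher gene. With the replicate number as a block 78 genes differed, 23 higher and 55 lower at 12 h. ACC oxidase 1 (Os02g0771600), which forms ethylene, changed by -1.62 ± 0.18, a cupin family protein (Os02g0532500) by -1.22 ± 0.11 and a lysine decarboxylase-like protein (Os09g0547500) by -1.10 ± 0.11. The rest of the 5 genes called without a block, chosen after their values were seen, were Os01g0731600 of no named product at -1.64 and a DUF6 protein (Os12g0518200) at -1.17, or -2.26 with processed signals. 0 of 246 ribosomal protein genes were called (0 adjusted over the list alone), with a median difference of 0.51 toward the untreated level (adjusted p = 1.45e-15, adjusted p = 0.257 with fry, 1e-24 to 0.608 over all alternatives, and adjusted p = 0.608 with an estimated correlation), a value that was 0.16 and 0.86 without the 8 h arrays of replicates 1 and 2 and 0.30 without the 12 h array of replicate 2. 0 of 14 JAZ/TIFY genes were called (10 adjusted over the list alone), with a median difference of -0.60 (adjusted p = 1.42e-06, and adjusted p = 0.252 with an estimated correlation), and of -0.40 without the 8 h array of replicate 1. The count of genes was 870 without the 8 h array of replicate 2, with 570 higher and 300 lower at 12 h, 3 without the 12 h array of replicate 1, all higher, 2 without either 6 h array and 0 without any single one of the other 8 arrays. Over all 6 times the moderated F test found 16460 genes, 66.1% of those tested, whose ratio differed between times. Of 180 tests of a list at a time, 116 were called with camera at its preset correlation, 165 with fry and 0 with an estimated correlation, where 53 had an unadjusted p under 0.05. Of 150 tests between consecutive times these counts were 61, 42, 0 and 27.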

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

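The test within 1 slide, the test on genes chosen on replicate 2 and the test of the untreated signal were chosen only after the result was seen. The ratio of treated over untreated RNA differed in 4236 genes between 1 and 2 h, in 6939 between 2 and 4 h, in 243 between 4 and 6 h, in 5 between 8 and 12 h and in 16460 genes over all times. Genes called with opposite directions at both times of a step numbered 130 from 1 to 2 h, 364 from 2 to 4 h and 19 from 4 to 6 h. Os04g0437300, a U box protein, stood at -1.72 ± 0.10 at 1 h and 1.00 ± 0.10 at 4 h, or 1.55 at 4 h with median centring.

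Late in the series replicate 2 showed smaller changes than replicate 1, with ribosomal medians at 8 h of -1.39 in replicate 1 and -0.66 in replicate 2. Against a uniform compression of the ratios stood the quotient of replicate 2 over replicate 1, which was 1 for the diterpenoid and MEP lists and 0.47 for ribosomal proteins, a difference of 0.53. Against a difference between slides, the spread of log2 ratios at 8 h had a quotient of 0.799 although both arrays lay on 1 slide. An earlier return toward the untreated level in replicate 2 may account for the pattern. Among genes changed at least 2-fold at 4 h, those that stayed had a change at 12 h at least as large as at 4 h. Those that returned had lost at least 1 log2 unit by 12 h, and genes in between were in neither set. Genes that stayed had a quotient at 6 h 0.25 above that of genes that returned when chosen on replicate 1 (776 and 2798 genes). The difference was 0.29 when they were chosen on replicate 2 (362 and 3463 genes). A difference between the cultures that was not tested stays open too. So does a fault of the 8 and 12 h arrays of replicate 1, or a different untreated RNA on them, which was not tested. These arrays had 81 and 82 outlier spots, against 12 and 9 in replicate 2. Smaller changes in replicate 2 were also seen at 6 h, on other slides.

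For 952 genes the change was under 2-fold, called in 1 direction at every time and not different between times, which dye effects of single probes could give. Of those with another probe, 194 of 220 shared the direction with it, or 88.2% (exact 95% interval 83.2 to 92.1). The comparison set had the same limits on size and direction but differed between times, and there 331 of 341 shared it, or 97.1%. The share of 88.2% argues against probe dye effects as the whole cause, and leaves a dye effect common to all probes of a gene open. No biological explanation was tested for it.

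Ribosomal protein genes had a lower ratio at 6 h. A ratio bias of bright spots as the source of the fall is argued against by genes outside the list of matched brightness. Their median without loess was 0.61 (bootstrap interval 0.53 to 0.67) against -0.67 for the list. Brightness was the mean over both channels and all arrays, so genes raised by the treatment could be among those matched, which limits the test. The size of the fall depended on loess, with which the list stood at -1.48 and -0.90 in replicates 1 and 2. At 1 and 2 h the sign of the list's median also depended on it. A change of the culture with time that the untreated RNA does not share cannot be told apart from the treatment, because the labels do not say whether untreated RNA was taken at each time. Untreated log2 signals of different times of 1 replicate on 1 slide differed by a median absolute deviation of 0.042 to 0.076. Between replicates on 1 slide it was 0.194 to 0.215. Within a replicate across slides it was 0.173 to 0.216 in replicate 1 and 0.118 to 0.139 in replicate 2. Pearson correlations across slides were 0.9769 to 0.9818 in replicate 1 and 0.9954 to 0.997 in replicate 2. Between the replicates at 1 to 6 h they were 0.9926 to 0.9949. The late untreated signals of replicate 1 thus stood apart, and the cause was not tested. A single untreated RNA per replicate would give the closeness seen within a slide, but RNA taken anew could too, so the question stays open. The untreated signal of the list moved by 0.104 from the 1 h to the 6 h arrays, the mean of 0.115 and 0.093 in the replicates.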

How the results depend on the processing

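Leaving out arrays of 8 and 12 h and the slide as a fixed block were alternatives chosen after seeing the data. Of the counts of genes and lists, 208 values over the other alternatives stayed within 1.5 times of the reported ones and 34 moved further. The cause was not tested, except that stricter thresholds call fewer genes by construction. With a 2-fold change required, the counts were 2706, 5297, 7716, 6929, 5884 and 3247 at the times in order, and 1303, 2111 and 115 for the steps from 1 to 2 h, 2 to 4 h and 4 to 6 h. At an adjusted p under 0.01 these steps had 1156, 2591 and 22 genes, and the step from 8 to 12 h had 0. Processed signals gave 49, 1 and 1 genes for the steps from 4 to 6, 6 to 8 and 8 to 12 h, and the deposited values gave 49, 2 and 1. For the step from 8 to 12 h, no background correction gave 3, the strict filter on dim probes 3 and the slide as a fixed block 9. With the slide as a random block (consensus correlation 0.021) each count stayed within 1.5 times. Fitted alone, the steps from 1 to 2, 4 to 6 and 8 to 12 h had 10284, 0 and 0 genes. Without the 8 and 12 h arrays of replicate 1 the counts were 7817 at 12 h, 450 from 4 to 6 h and 0 from 8 to 12 h, and without all 8 and 12 h arrays 450 from 4 to 6 h. With an estimated correlation 0 lists were called at single times and 0 between times. With the replicate number as a block the steps from 1 to 2, 4 to 6 and 8 to 12 h had 7045, 842 and 78 genes, the last with 23 higher and 55 lower at 12 h. Same-numbered arrays of different times had deviations with correlations from -0.017 to 0.825, 11 of 15 over 0.1. Since a value over 0.1 had been asked of each of them, the numbers were not taken to pair the samples. Only the pairs of 2 h with later times fell short of it. Pairs of 1 h with other times had 0.12 to 0.35, and pairs among the times from 4 h on 0.228 to 0.825. Untreated signals on 1 slide were also closer within a replicate number (median deviation 0.056) than between numbers (0.202). Both are hints of deviations shared by number, so that the step counts without the block may be too low. The 6 residual degrees of freedom would then not be independent. In that case p-values against untreated RNA at single times can be too small, and the counts at single times too high.

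Leaving out 1 array at a time, where a time left with 1 array is assumed to vary like the others, gave ranges of 5571 to 10779 at 1 h, 11355 to 16916 at 2 h, 15727 to 19034 at 4 h, 14864 to 18435 at 6 h, 12664 to 17599 at 8 h and 6831 to 14288 at 12 h. The steps ranged over 667 to 5166, 1745 to 7840, 6 to 318, 0 to 0 and 0 to 870 genes in order of time, the F test over 13050 to 17312, list calls over 112 to 120 and list calls between times over 57 to 63. Among list values, 4844 stayed on their side of the threshold, 290 lost and 140 gained a call with their direction kept over the other alternatives, and 3838, 62 and 55 with an array left out. For the named genes, some of which were exchanged after such results had been seen, these numbers were 4178, 38 and 45, and 5516, 133 and 37 with an array left out. Among the values reversed with median centring were the ribosomal medians at 1 h (0.32) and 2 h (0.12), Os04g0683700 at 8 h (0.27) and, not called before, Os03g0438100 at 8 and 12 h (0.50 and 0.32), Os02g0570700 at 2 h (-0.41) and Os12g0518200 at 12 h (-0.33). The medians of cell division at 1 h and of auxin response at 4 h also turned from below to above 0 with median centring. Fry called the auxin response list at 2 and 4 h (medians -0.0253 and -0.0737) and the photosynthesis list at 4 h (-0.0599) against the direction of camera, which had not called them. Leaving out an array reversed the ribosomal step from 6 to 8 h, whose values then went up to 0.48, without the 6 h array of replicate 1 (-0.15) and without the 8 h array of replicate 2 (-0.21) and, not called before, the ribosomal step from 4 to 6 h without the 6 h array of replicate 1 (0.10, in a range from -0.47) and Os02g0569900 at 1 h without the 1 h array of replicate 1 (0.44, in a range from -0.58). The direction of camera, though not the sign of the median in these cases, turned for the WRKY step from 4 to 6 h without the 6 h array of replicate 2 (median -0.0729, in a range of -0.28 to -0.0574) and for the cell division step from 6 to 8 h, not called before, without the 8 h array of replicate 1 or without its 8 and 12 h arrays (median 0.145 in both, in a range from -0.103). Signal over background limits weak probes, since between 78.4% and 83.1% of gene spots were well above background in Cy5.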

Other observations

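The lists not yet described held genes that went both ways. Of the beta-1,3-glucanases, enzymes that cut a wall polymer of fungi and plants, 18 of 28 rose and 5 fell at 8 h, 24 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0324, adjusted p = 0.318 with an estimated correlation and 0.463 with median centring). Over all alternatives it ranged from 2.47e-05 to 0.463. The adjusted p was 0.0727 without the 8 h array of replicate 2 and 0.128 with the strict filter on dim probes, and the median 0.88 with processed signals and 0.29 without a filter. Class III peroxidases rose in 37 of 93 genes and fell in 4 at 1 h, 42 adjusted over the list alone, with a median of 0.35 (adjusted p = 7.47e-05, adjusted p = 0.149 with an estimated correlation and 0.096 with median centring, 3.97e-07 to 0.149 over all alternatives), and 0.15 without the filter on dim probes. Glucosyltransferases rose in 40 of 115 genes and fell in 16 at 12 h, 55 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.0382, adjusted p = 0.209 with an estimated correlation and 0.863 with median centring, 3.13e-05 to 0.863 over all alternatives). Without the 12 h array of replicate 2 the median was 0.22 (adjusted p = 0.0508), and without the filter on dim probes 0.08 (adjusted p = 0.0801). In the photosynthesis list 27 of 75 genes fell and 11 rose at 12 h, 38 adjusted over the list alone, with a median of -0.24 (adjusted p = 0.0344, and adjusted p = 0.32 with an estimated correlation). The median was -0.13 without the 12 h array of replicate 1, -0.51 with median centring and -0.62 with processed signals (adjusted p = 0.0887), and the adjusted p was 0.0666 without and 0.0534 with a strict filter on dim probes, in a range of 2.25e-05 to 0.32 over all alternatives. The cells grew in the dark, and 30 of the entries were plastocyanin-like proteins, which are not part of photosynthesis by that name.

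Other lists did not pass camera at any time, while fry, which does not compare a list with other genes, called some of them at single times. MYB factors had 60 genes higher and 31 lower of 127 at 2 h, 93 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.0956). Heat shock genes had 36 higher and 18 lower of 66 at 4 h, 54 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.0547). The adjusted p was 0.0277 with processed signals, 0.047 without background correction, 0.0206 without the 4 h array of replicate 1, 0.0494 without the 1 h array of replicate 1, 0.0491 without the 8 h array of replicate 1, 0.0498 with the strict filter on dim probes and 0.0496 with the slide as a fixed block, in a range of 1.87e-05 to 0.34 over all alternatives. Auxin response genes had 26 higher and 25 lower of 64 at 4 h, 51 adjusted over the list alone, with a median of -0.07 and a mean of the other sign, 0.04, against a median of 0.17 with median centring (adjusted p = 0.987). Genes of cell wall expansion had 15 higher and 32 lower of 61 at 6 h, 49 adjusted over the list alone, with a median of -0.35 (adjusted p = 0.107), from -0.38 in replicate 1 and -0.17 in replicate 2, or -0.04 without the filter on dim probes. The sugar starvation list had 3 higher and 4 lower of 9 at 6 h, 7 adjusted over the list alone, with a median of -0.41 and a mean of 0.14, against a median of 0.03 without the filter on dim probes (adjusted p = 0.858). The replicates differed in sign, with medians of 0.05 in replicate 1 and -0.70 in replicate 2. Its alpha-amylase Os08g0473900 stood at 4.85 ± 0.49. Respiratory burst and antioxidant genes had 21 higher and 13 lower of 44 at 8 h, 34 adjusted over the list alone, with a median of 0.26 (adjusted p = 0.129). The respiratory burst oxidase homolog Os01g0360200, of the enzymes that make superoxide, stood at 0.69 ± 0.26 at 1 h and did not pass the test at any time. At 1 h its adjusted p was 0.0238 with median centring, 0.0216 without either 6 h array, 0.0248 without either 8 h array, 0.0401 with the replicate number as a block and 0.0371 without the 8 and 12 h arrays of replicate 1, in a range of 0.0216 to 0.273 over all alternatives. At 8 h it was 0.0255 with median centring, 0.0314 without the 8 h array of replicate 1 and 0.0455 without the 8 and 12 h arrays of that replicate, in a range of 0.0255 to 0.709.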
